A study of Homo sapiens with 12 samples.

How the data were processed

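RNA sequencing was measured in 12 libraries of A549 cells, a human lung adenocarcinoma line, in 4 groups of 3. The groups were unmodified cells (WT), cells in which YTHDF1 was knocked out (YTHDF1 KO), cells in which small interfering RNA had silenced ARID1A (siARID1A), and cells with both changes (YTHDF1 KO plus siARID1A, called the combined group). Groups were taken from the genotype field of the labels. The sample titles call the YTHDF1 arm a knockdown where the genotype field and the series design call it a knockout, no label says whether these cells were a clone or a pool, and none names a control small interfering RNA. Replicate numbers run from 1 to 3 in every group, and nothing in the labels says that libraries of 1 number share a day or a culture, or that libraries of 1 group come from separate cultures. The p-values therefore measure the spread between libraries only.

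Per the labels, total RNA was made into stranded libraries, and the authors processed the reads with Trim Galore 0.6.6, STAR 2.7.0d, featureCounts 2.0.1 and edgeR 3.32.1 on GRCh38. The authors deposited 1 table of raw counts, with 60617 Ensembl genes in it and 1 column of counts per library. The annotation release and the strand setting of the counting are not stated, so counts of genes that overlap another gene on either strand, or that have close paralogs or pseudogenes, are uncertain. The values were whole numbers, and library totals ran from 30220717 to 45042635. Symbols came from a table of gene names (60261 identifiers), positions and gene types from GENCODE 29 (58542 identifiers), 21 identifiers were in neither, and 1217 kept their identifier because another gene had the same symbol.

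Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. All 12 libraries went into 1 fit with 1 coefficient per group, after filterByExpr on the 4 groups (18524 genes tested, 42093 left out) and TMM scaling (factors 0.912 to 1.055). The test was the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested in each comparison and a threshold of 0.05. The common dispersion was 0.0089, a biological coefficient of variation of 9.44%. The comparisons were 5 pairwise contrasts and the interaction, which is the change with siARID1A in the knockout minus the change with siARID1A in WT. Standard errors of log2 fold changes come from the replicate standard deviations of log2 CPM (edgeR's cpm on TMM-scaled library totals) with a prior count of 2. Where a group had 0 counts of a gene in all 3 libraries, the fold is a lower bound against a floor of 3 counts over the group (0.0256 CPM in WT). Where a group had 1 to 3 counts, a ratio with a 95% exact binomial counting interval is given in place of the fitted fold change. Intervals and floors cover counting error only.

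Lists of genes were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except where a choice is said to have been made later. The 31 lists tested were interferon-stimulated genes, nucleic acid sensing and interferon induction, inflammatory cytokines and chemokines, NF-kB response genes, MHC class I and MHC class II antigen presentation, immune checkpoint ligands and related surface proteins, R-loop processing factors, DNA damage checkpoint and repair, p53 target genes, G2/M and mitosis, DNA replication and S phase, SWI/SNF subunits, N6-methyladenosine writers, erasers and readers, epithelial to mesenchymal transition, extracellular matrix, AP-1 and immediate early genes, NRF2 target genes, cholesterol biosynthesis and uptake, hypoxia and glycolysis, the integrated stress and unfolded protein response, cytosolic ribosomal proteins, translation factors, nuclear-encoded oxidative phosphorylation genes, alveolar epithelial and A549 lineage genes, Hippo-YAP target genes, markers of blood, stromal and other non-epithelial cells, mitochondrially encoded transcripts, replication-dependent histones, the heat shock response, and lysosome and autophagy genes. All 1070 list genes were matched to the table. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over 186 tests (31 lists in 6 contrasts), and again with an estimated correlation and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone. In the text, a list's adjusted p is camera's.

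Named genes followed a rule. They were YTHDF1 and ARID1A. For each pairwise contrast they were the 6 largest rises and 6 largest falls among genes past the threshold with a symbol, a mean of at least 10 CPM over the 2 groups and no overlap between the groups' libraries. For the interaction they were the 5 most positive and 5 most negative by the mean over all groups. Of each list, up to 4 members past the threshold with the smallest p were taken. YTHDF2, YTHDF3 and ARID1B were added as relatives of the targets, and CGAS, STING1, IFNB1, CXCL10, CCL5, ISG15, IFIT1, CD274 and B2M among the genes of the immune themes in the series title. A few genes that the rule takes are not reported here.

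Fold changes of different contrasts were compared across the 18524 genes by Pearson's r with a jackknife standard error over libraries, and by the overlap of calls against the product of the list sizes over the genes tested. Each jackknife fit was filtered anew (19120 to 19329 genes), so this standard error also holds a change of genes. The contrasts of YTHDF1 KO and of siARID1A share the WT libraries, so their correlation and covariance stand beside those of 20 simulations of unchanged groups. Splits of the libraries into other groups were refitted, 10 per pairwise contrast and 60 for the interaction. After the first results were seen, log2 fold changes of 10432 protein-coding genes with a mean of at least 5 CPM were summarised by chromosome and in windows of 40 neighbouring genes. Log2 fold change (limited to 2 in size) was regressed on presence of each 7-mer in 3′ UTRs of at least 50 bases. Terms for UTR length, GC content and expression were included. In 11095 genes with a mean of at least 3 CPM, this gave a z for 16082 7-mers found in at least 100 genes.

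The procedures were tested on simulated data. With 50 genes changed at each of 4 sizes among 17982, the KO contrast recovered 8 at 1.25-fold, 26 at 1.5-fold, 31 at 2-fold and 40 at 4-fold, with 11 false calls (9.48% of calls). The interaction recovered 23 at 1.5-fold, 28 at 2-fold, 38 at 4-fold and 44 at 8-fold, with 6 false calls (4.32%). A list shifted by 1.5-fold was found, and 0 of 30 other lists were called. Simulated genes varied independently of each other, so that run does not test camera's preset correlation. A planted 7-mer shift of -0.15 ranked first in 10 of 10 runs. A chromosome shift of -0.4 was recovered between -0.457 and -0.381 in 20 runs.

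Alternatives were DESeq2-style (RLE) size factors in edgeR, library totals without a factor, no filter, a filter at a mean of 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom, fits of the compared groups alone, the replicate number as a block, counts thinned to the smallest library, and leaving out each library. Fits without the genes of chromosomes 2 and 9 and without mitochondrially encoded genes were added after the data were seen. Nothing was left out of the deposited columns.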

Results

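The series measured RNA levels in A549 cells, a human lung adenocarcinoma line, by sequencing 12 libraries in 4 groups of 3. YTHDF1, a protein that binds N6-methyladenosine in RNA, was knocked out per the genotype labels, ARID1A, a subunit of the SWI/SNF (BAF) chromatin remodeller, was silenced with small interfering RNA, or both were done. Library totals were 43922216, 45042635 and 33970369 counts for WT replicates 1 to 3, and 37371148, 41186530 and 35074776 for YTHDF1 KO. They were 33584291, 32380546 and 33704679 for siARID1A, and 30220717, 41396019 and 37809386 for the combined group. Values are CPM as mean ± SD (n = 3) or log2 fold changes. The series title names YTHDF1, R-loops, innate immune restraint and adaptive immune resistance, so genes of these themes are given in every comparison.

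The transcripts of both targeted genes were lower in the groups labelled for them. YTHDF1 (ENSG00000149658, chromosome 20, 63195429 to 63216234, GRCh38) stood at 88.2 ± 2.57 CPM in WT, 24.9 ± 2.08 in YTHDF1 KO (28.2% of WT), 97.9 ± 4.69 in siARID1A and 30.95 ± 1.11 in the combined group (35.1%). ARID1A (ENSG00000117713, chromosome 1, 26693236 to 26782110) stood at 164 ± 14.1 CPM in WT, 161 ± 12 in YTHDF1 KO, 42.5 ± 2.12 in siARID1A (25.9%) and 54.2 ± 6.51 in the combined group (33.1%). YTHDF1 fell by 1.83 on the log2 scale in YTHDF1 KO (SE 0.075, adjusted p = 6.47e-16) and ARID1A by 1.95 in siARID1A (adjusted p = 1.03e-14). Both were somewhat higher in the combined group than in the group with that change alone, YTHDF1 by 0.32 (adjusted p = 0.00323) and ARID1A by 0.35 (adjusted p = 0.00214). ARID1A did not change with YTHDF1 KO by this test (-0.03, adjusted p = 0.809), nor YTHDF1 with siARID1A (0.15, adjusted p = 0.0925).

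**Figure D1:**
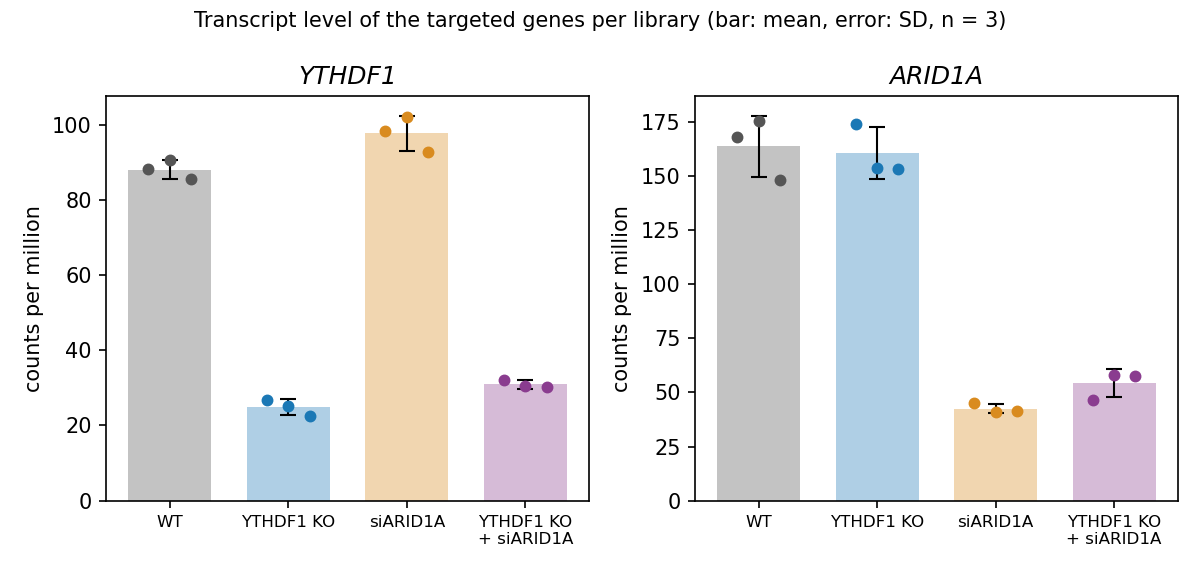
YTHDF1 and ARID1A in CPM (y axis) for the 4 groups (x axis). Bars are means, error bars SD and points the 3 libraries. YTHDF1 sits at 24.9 and 30.95 CPM in the knockout groups against 88.2 in WT, and ARID1A at 42.5 and 54.2 CPM in the siARID1A groups against 164 in WT.

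Libraries grouped by label in the first 2 principal components of log2 CPM (41.5% and 25.5% of the variance). WT replicate 2 stood apart in its mitochondrial share, 4.85% of counts against 7.90% and 8.23% in the other WT libraries and 6.81% to 7.75% in the other groups. It also stood apart in its counts as a whole, mitochondrial genes included. Chi-square per degree of freedom was 56.7 and 55.09 against WT replicates 1 and 3, and 13.79 between those. Within the other groups it ran from 3.475 to 14.29. Lists that newly passed in at least 1 comparison without WT replicate 2 were ribosomal proteins, oxidative phosphorylation, translation factors, mitochondrially encoded transcripts, hypoxia, the stress and unfolded protein response, cholesterol, epithelial to mesenchymal transition and MHC class I. Without it, the ribosomal list was lower in YTHDF1 KO than in WT (adjusted p = 7.2e-10, the lowest over the alternatives, which ran up to 0.806, against 0.171 with all libraries). So were oxidative phosphorylation genes (0.014, with alternatives up to 0.959, against 0.453).

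Genes of chromosomes 2 and 9 shifted as blocks between groups. The 715 expressed genes of chromosome 2 lay below WT in YTHDF1 KO by a median of -0.447 relative to the other chromosomes (a ratio of 0.734), and 88.3% of them were below the median of the others. All 17 windows of neighbouring genes had a median below 0. The same genes lay at 0.008 in siARID1A vs WT and at -0.480 in the combined group vs siARID1A. The 431 genes of chromosome 9 lay at -0.437 in YTHDF1 KO, -0.434 in siARID1A and -0.480 in the combined group, each against WT, and at 0.000 in the combined group vs YTHDF1 KO. On chromosome 9 in siARID1A, the windows from 71911510 to 136687423 had medians of -0.673 to -0.358, and the 3 windows before them -0.097 to -0.004. Medians of the 21 other chromosomes (among them X) lay between -0.099 and 0.110 in YTHDF1 KO vs WT and between -0.083 and 0.106 in siARID1A vs WT. In YTHDF1 KO vs WT, 71.2% of the chromosome 2 genes and 66.1% of the chromosome 9 genes were called lower, against 20.3% elsewhere. Named genes on chromosomes 2 and 9 are given with their chromosome where they are first named.

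**Figure D2:**
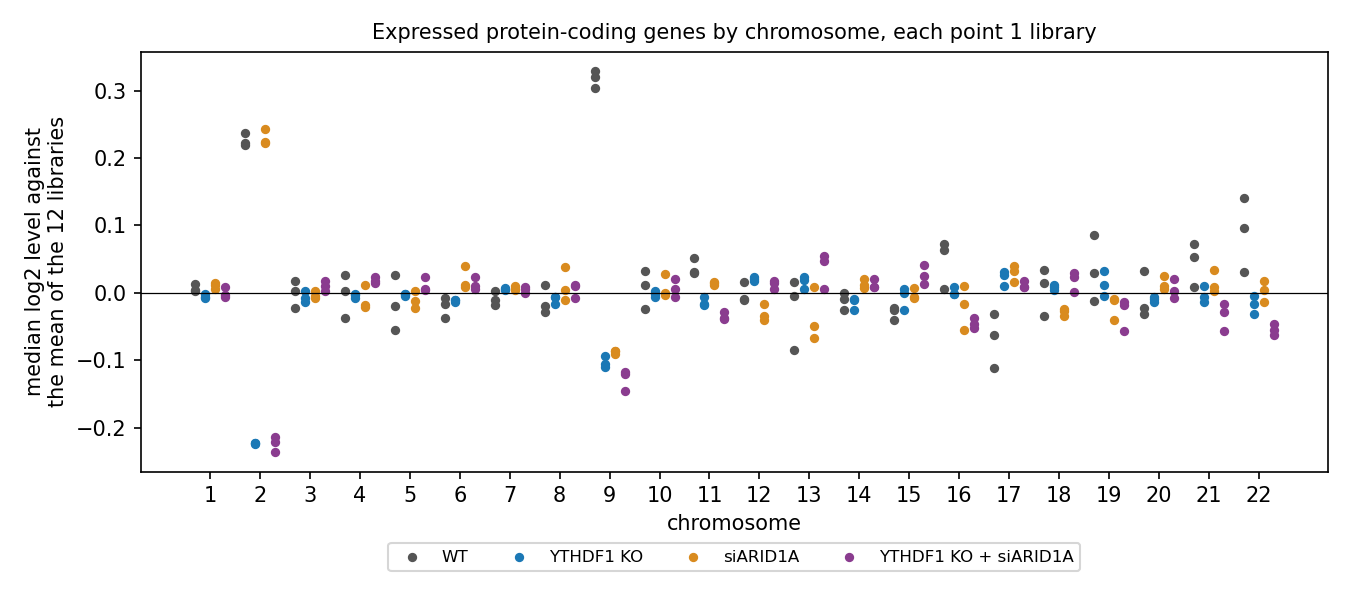
Median log2 level (y axis) of expressed protein-coding genes of each autosome (x axis), against the mean of the 12 libraries, each point 1 library coloured by group. Chromosome 2 sits between 0.219 and 0.244 in WT and siARID1A and between -0.237 and -0.214 in both YTHDF1 KO groups, and chromosome 9 between 0.304 and 0.330 in WT alone.

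**Figure D3:**
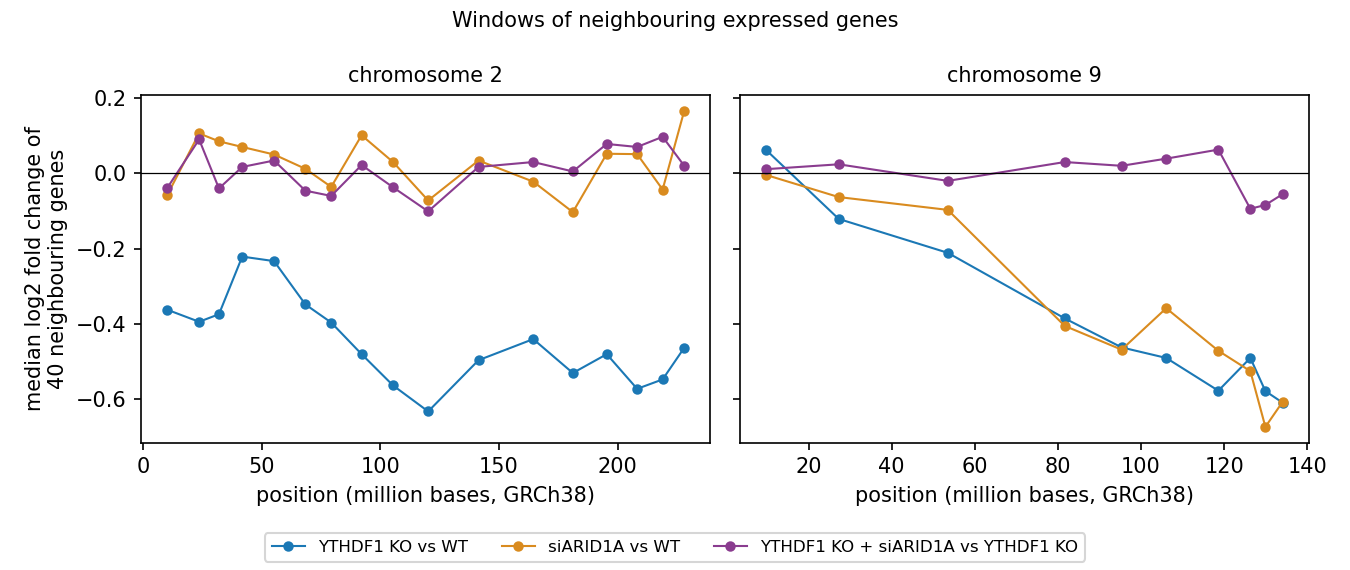
Median log2 fold change (y axis) of 40 neighbouring expressed genes along chromosomes 2 and 9 (x axis, Mb), 1 line per comparison. On chromosome 9 the line of siARID1A vs WT runs from -0.004 in its first window to -0.606 in its last, and that of the combined group vs YTHDF1 KO stays between -0.094 and 0.063.

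The comparison of YTHDF1 KO with WT asked how cells labelled as knocked out for YTHDF1, whether a clone or a pool is not stated, differed from WT. Interferon-stimulated genes rose, some of them from near silence in WT. IFIT1, which binds foreign RNA ends, rose from 1.90 ± 0.201 to 159 ± 1.81 CPM (log2 fold change 6.40, SE 0.088), and the ubiquitin-like modifier ISG15 by 4.28 (SE 0.239). The T cell chemokine CCL5 had 2 counts in WT and 5173 in YTHDF1 KO, a ratio of 2630 (95% interval 728 to 21700). FER1L6, a ferlin, was nearly lost, from 84.0 ± 2.81 to 0.193 ± 0.088 CPM. Of 18524 genes tested, 3630 rose and 3859 fell, 1053 and 1180 of them by more than 1 on the log2 scale.

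Of 51 measured interferon-stimulated genes, 47 rose, 2 fell and 2 did not pass, with the same counts adjusted over the list alone (adjusted p = 3.55e-93). Their median log2 fold change was 2.18, or 2.15 with the 4 members near 0 counts in WT at their bound. The dsRNA-activated synthetase OAS2 rose by 9.26 from 0.0314 CPM in WT, IFIT2 by 7.16, OASL by 6.84 and IFI6 by 5.66. Nucleic acid sensing and interferon induction genes rose in 15 of 29 and fell in 4 (16 and 4 adjusted over the list alone, adjusted p = 2.52e-07). The RNA sensors IFIH1 (chromosome 2) and RIGI (chromosome 9) rose by 3.74 and 1.95. Transcripts of the interferons IFNB1 (chromosome 9), IFNL1 and IFNL3 had 0 counts in WT and were at least 32.3-fold, 132-fold and 160-fold higher in YTHDF1 KO. The DNA sensor CGAS lay at 1.55 without passing (adjusted p = 0.314), and its adaptor STING1 rose by 2.0. Of 24 cytokines and chemokines, 14 rose and 5 fell, also adjusted over the list alone (adjusted p = 2.2e-11). The neutrophil attractants CXCL1 and CXCL5 rose by 2.81 and 2.94, CXCL10 was at least 175-fold higher, and CXCL11 had a ratio of 285 (95% interval 78.4 to 2360).

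NF-kB response genes rose in 15 of 20 and fell in 1, also adjusted over the list alone, among them IER3 (1.68) and the NF-kB subunits NFKB2 (1.07) and RELB (0.94). Their adjusted p was 2.45e-06, and adjusted p = 0.158 with an estimated correlation. Of 21 MHC class I genes, 12 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00358, and adjusted p = 0.184 with an estimated correlation). HLA-B rose by 2.07, the light chain B2M by 0.66 and the peptide transporter TAP1 by 0.72. Checkpoint ligands went both ways, 9 up and 4 down of 21, also adjusted over the list alone (adjusted p = 0.262). CD274, which encodes PD-L1 on chromosome 9, rose by 1.62 from 0.672 CPM, NT5E rose by 1.17 and LGALS9 fell by 2.23. Of 5 MHC class II genes, 2 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.467).

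**Figure D4:**
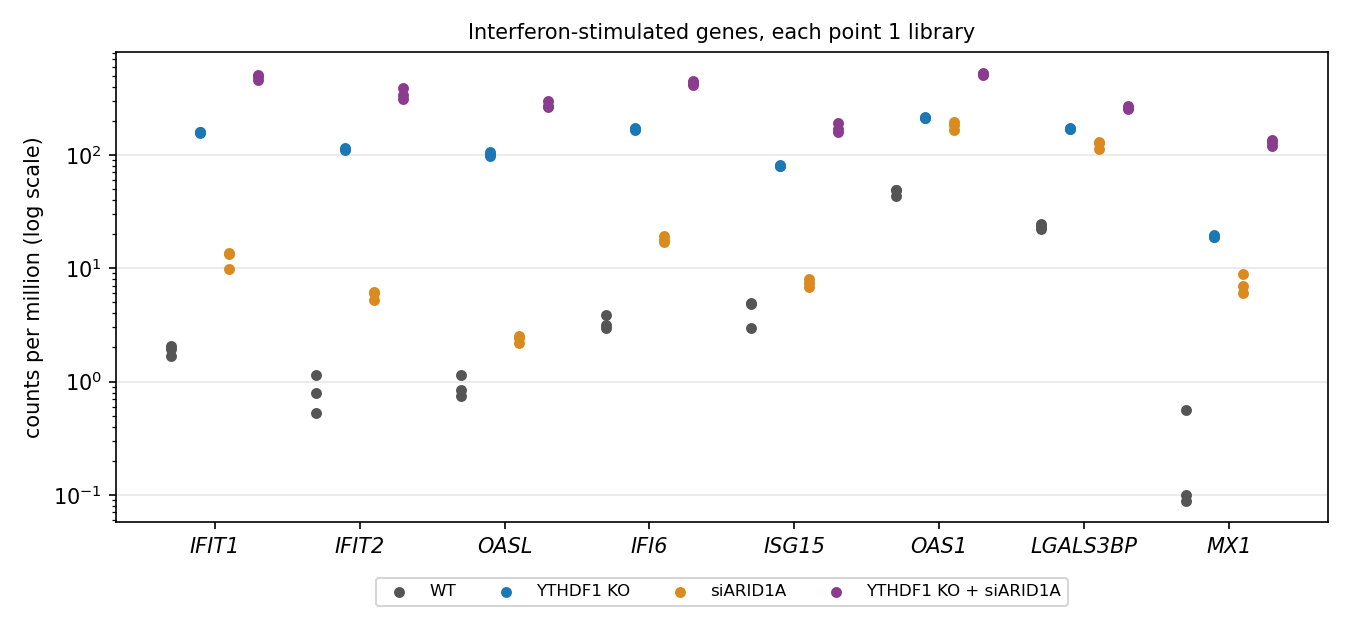
CPM on a log scale (y axis) of 8 interferon-stimulated genes (x axis), each point 1 library, coloured by group. IFIT1 has means of 1.90, 12.2, 159 and 487 CPM in WT, siARID1A, YTHDF1 KO and the combined group, and MX1 of 0.251, 7.28, 19.1 and 129 CPM.

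NRF2 target genes, which serve redox balance and detoxification, fell in 23 of 31 and rose in 4, also adjusted over the list alone. Their median was -0.60 (adjusted p = 4.29e-14, and adjusted p = 0.114 with an estimated correlation). The aldo-keto reductases AKR1B10, AKR1C2 and AKR1C3 fell by 2.92, 2.66 and 2.02, AKR1B10 from 2614 to 346 CPM. G2/M genes fell in 26 of 40 and rose in 1 (31 and 1 adjusted over the list alone), with a median of -0.32 (adjusted p = 0.000883, and adjusted p = 0.579 with an estimated correlation). Members that fell included NCAPH (-0.86), BUB1 (-0.78) and CENPA (-0.75), all on chromosome 2. AP-1 and immediate early genes rose in 15 of 26 and fell in 5 (16 and 6 adjusted over the list alone, adjusted p = 0.000222, and adjusted p = 0.184 with an estimated correlation). The MAP kinase phosphatase DUSP4 rose by 1.52 and ETV4 by 1.72, and DUSP1 fell by 1.30. Alveolar and A549 lineage genes had a median of -0.52, 11 of 23 falling and 7 rising (11 and 9 adjusted over the list alone, adjusted p = 0.0192, and adjusted p = 0.211 with an estimated correlation). Falls were seen for the liver-gut regulator HNF4A (-1.86) and the keratin KRT8 (-1.69), and a rise for CAV1 (1.16).

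Matrix genes split, 16 of 36 rising and 14 falling (17 and 15 adjusted over the list alone). LUM rose by 6.21 and THBS1 by 1.44, while the basement membrane collagens COL4A1 and COL4A2 fell by 1.86 and 1.75. That list's adjusted p was 0.0414, and adjusted p = 0.541 with an estimated correlation. Over the alternatives it ran from 0.0166 to 0.253, and it did not pass without WT replicate 1 (0.0631), WT replicate 3 (0.182) or siARID1A replicate 1 (0.0535), or without the genes of chromosomes 2 and 9 (0.253). Lysosome and autophagy genes rose in 19 of 37 and fell in 5 (20 and 5 adjusted over the list alone), with CTSL (chromosome 9) at 1.05 and CTSD at -0.92. Their adjusted p was 0.0401, adjusted p = 0.461 with an estimated correlation, and 0.0558 and 0.0575 without WT replicate 3 and YTHDF1 KO replicate 2. It was 0.215 without the genes of chromosomes 2 and 9, the highest of the alternatives (from 0.0171). R-loop factors rose in 4 of 40 and fell in 10, also adjusted over the list alone (adjusted p = 0.53), with a median of -0.086 that was 0.005 with library totals. The endonuclease ERCC4 and BRCA1 rose by 0.76 and 0.71, and the helicase DDX1 (chromosome 2) fell by 0.50. Of 76 ribosomal protein genes, 0 rose and 12 fell (0 and 9 adjusted over the list alone, adjusted p = 0.171), RPL7A (chromosome 9) and RPS7 (chromosome 2) by 0.80 and 0.61. Of 25 N6-methyladenosine factors, 0 rose and 4 fell (0 and 2 adjusted over the list alone, adjusted p = 0.964), with a median of 0.03 and a mean of -0.009. The relatives YTHDF2 (0.07, adjusted p = 0.466), YTHDF3 (0.15, adjusted p = 0.0619) and ARID1B (0.13, adjusted p = 0.185) did not pass.

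Other large falls were of the neurotrophin receptor NTRK3 (-6.95, from 224 ± 26 to 1.81 ± 0.313 CPM), the cytochrome P450 CYP4F11 (-6.10), the adhesion protein TENM2 (-5.49), the secreted kinase PKDCC (chromosome 2, -5.18) and the membrane protein TM4SF4 (-4.64). With library totals in place of TMM factors, 61.2% of the called genes were higher (4765 against 3016 lower), compared with 48.5%.

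With no labelled control small interfering RNA, the comparison of siARID1A with WT asked how cells labelled for silencing of ARID1A differed from WT. Here p53 target genes and interferon-stimulated genes rose together. The cell cycle inhibitor CDKN1A rose by 1.54, from 158 to 459 CPM, and the stress enzyme HMOX1 by 2.62, from 275 to 1686 CPM. The chaperone HSPA5 (chromosome 9) fell by 1.43, from 1981 to 735 CPM. Of the genes tested, 4100 rose and 4268 fell, 1517 and 686 of them by more than 1. With library totals 57.1% of the called genes were higher (4683 against 3512 lower), compared with 49%. RLE factors gave 52.2% (4346 against 3982).

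Of 35 p53 target genes, 29 rose and 2 fell, also adjusted over the list alone, with a median of 0.91 (adjusted p = 9.78e-25). FDXR rose by 2.03, TP53INP1 by 2.02 and TP53I3 (chromosome 2) by 1.64. Interferon-stimulated genes rose in 36 of 51 and fell in 1 (39 and 1 adjusted over the list alone), with a median of 1.18 (adjusted p = 2.97e-25). IFIT1 rose by 2.7 (SE 0.172) to 12.2 ± 2.07 CPM, IFI6 by 2.42, LGALS3BP by 2.40 and OAS1 by 1.95, and ISG15 by 0.82. CCL5 had 24 counts against 2 in WT, a ratio of 14.2 (95% interval 3.53 to 124). IFNB1 had 0 counts in both groups, and CXCL10 stood at 0.0793 CPM against 0 counts in WT. STING1 rose by 1.56, CGAS by 3.99 and CD274 (chromosome 9) by 1.03. Of 29 sensing genes, 12 rose and 1 fell, also adjusted over the list alone, with a median of 0.24 or 0.14 with members near 0 counts at their bound. That list's adjusted p was 0.0306, adjusted p = 0.184 with an estimated correlation, and 0.0507 without siARID1A replicate 2. It was 0.119 without the genes of chromosomes 2 and 9, the highest of the alternatives (from 0.0187). Cytokines rose in 13 of 24 and fell in 4 (13 and 5 adjusted over the list alone, adjusted p = 0.0603), with IL11 falling by 2.11.

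NF-kB response genes rose in 13 of 20 and fell in 2 (14 and 2 adjusted over the list alone), with NFKBIE at 1.62 and the inhibitor TNFAIP3 at 1.63. Their adjusted p was 5.88e-08, and adjusted p = 0.121 with an estimated correlation. MHC class I genes rose in 14 of 21 and fell in 2 (15 and 2 adjusted over the list alone), PSMB9 and PSMB8 by 1.88 and 1.55 and B2M by 0.23. That list had adjusted p = 0.000847, and adjusted p = 0.126 with an estimated correlation. G2/M genes fell in 38 of 40 and rose in 0, also adjusted over the list alone, with a median of -0.57 (adjusted p = 4.2e-14, and adjusted p = 0.251 with an estimated correlation). S phase genes fell in 41 of 47 and rose in 1, also adjusted over the list alone (adjusted p = 2.65e-14, and adjusted p = 0.219 with an estimated correlation). The spindle checkpoint kinase BUB1B fell by 0.95, the helicase subunit MCM5 by 0.91 and the histone mRNA binding protein SLBP by 1.64, from 63.2 to 20.3 CPM.

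DNA repair genes fell in 33 of 50 and rose in 4 (35 and 4 adjusted over the list alone, adjusted p = 2.61e-08, and adjusted p = 0.184 with an estimated correlation). XRCC5 on chromosome 2, the Ku80 subunit of end joining, fell by 2.01 from 529 to 131 CPM, and BRCA2 by 0.98. R-loop factors fell in 26 of 40 and rose in 1 (27 and 2 adjusted over the list alone, adjusted p = 1.1e-05, and adjusted p = 0.211 with an estimated correlation). DDX21, FANCD2 and PARP1 fell by 0.94, 0.86 and 0.73. The stress and unfolded protein list fell in 24 of 34 and rose in 2 (25 and 3 adjusted over the list alone, adjusted p = 1.17e-16, and adjusted p = 0.0659 with an estimated correlation). The serine synthesis enzymes PSAT1 (chromosome 9) and PHGDH fell by 1.89 and 1.77, and the disulfide isomerase PDIA6 (chromosome 2) by 1.88. Lysosome and autophagy genes rose in 22 of 37 and fell in 1, also adjusted over the list alone (adjusted p = 7.96e-08, and adjusted p = 0.108 with an estimated correlation), the autophagy receptor SQSTM1 by 1.37.

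Replication-dependent histones rose in 10 of 27 and fell in 0, also adjusted over the list alone, H1-2 by 1.30 and H2AC6 by 0.72 (adjusted p = 0.03, and adjusted p = 0.347 with an estimated correlation). Matrix genes rose in 19 of 36 and fell in 11, also adjusted over the list alone, COL4A5 by 1.99 and LAMB3 by 1.32 (adjusted p = 0.00312, and adjusted p = 0.409 with an estimated correlation). Of 25 SWI/SNF subunits, 2 rose and 12 fell, also adjusted over the list alone (adjusted p = 0.0548, and 0.0322 to 0.104 over the alternatives), PBRM1 by 0.60. That list passed without the genes of chromosomes 2 and 9 (0.0396). It also passed without WT replicate 3 (0.0326), YTHDF1 KO replicate 2 (0.0489), or siARID1A replicates 1 (0.0397) or 2 (0.0322). The paralog ARID1B fell by 0.38 and YTHDF2 by 0.25, and YTHDF3 lay at 0.09 (adjusted p = 0.255). Cholesterol genes rose in 4 of 25 and fell in 13, also adjusted over the list alone (adjusted p = 0.0712), with DHCR7 falling by 0.69. Hypoxia and glycolysis genes split, 14 up and 11 down of 36 (14 and 12 adjusted over the list alone, adjusted p = 0.355, median -0.08, mean 0.036), HK1 rising by 1.60. Translation factors rose in 7 of 42 and fell in 15, also adjusted over the list alone (adjusted p = 0.235), with a median of -0.044 that was 0.02 with library totals. Of 47 oxidative phosphorylation genes, 2 rose and 10 fell (2 and 7 adjusted over the list alone, adjusted p = 0.687), with a median of -0.009 that was 0.015 with RLE factors and 0.057 with library totals. Of 13 mitochondrially encoded transcripts, 1 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.788), and without WT replicate 2 the list was lower than WT (adjusted p = 4e-04, against up to 0.848 over the alternatives). Markers of other cells rose in 3 of 10 and fell in 1, also adjusted over the list alone (adjusted p = 0.146), the smooth muscle actin ACTA2 by 2.7.

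Among genes with a mean of at least 10 CPM over the groups compared, and no overlap between their libraries, the largest rises were of the prostaglandin synthase PTGS2 (4.30, 13.2 ± 2.93 to 258 ± 78.5 CPM), FGFBP1 (4.13), MYPN (3.62), the muscle ankyrin repeat protein ANKRD1 (3.58), the neuropeptide receptor NPY1R (3.39) and FA2H (3.22). FER1L6 fell by 8.25, TENM2 by 6.95, the mucin MUC5B by 4.33, TINAGL1 by 2.81, PKDCC (chromosome 2) by 2.75 and NTRK3 by 2.74. Among 16082 7-mers in 3′ UTRs, TCAAGAA went with the lowest fold changes in siARID1A vs WT (z -8.61) and ranked second lowest in the combined group vs YTHDF1 KO (z -8.21), with z 0.41 in YTHDF1 KO vs WT and 3.68 in the combined group vs siARID1A. The 596 genes with CTCAAGAA had a median of -0.181 in siARID1A vs WT, and 47.7% of them were called lower, against 28.7% of genes without either of its 7-mers. XRCC5, PDIA6, CTNNB1 and KRT80 carry it.

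The comparison of the combined group with WT gave the largest number of changed genes, 4742 rising and 4795 falling, 1752 and 1355 of them by more than 1. Interferon-stimulated genes rose, IFIT1 to 487 ± 26.8 CPM (log2 fold change 8.01, SE 0.099) and OAS2 to 106 ± 4.48 CPM (11.46, SE 0.305). OAS2 stood at 0.0314 CPM in WT, close to the floor of 0.0256 CPM. Its SE, taken with a prior count of 2, does not cover the counting error at so low a level. MHC class I genes rose with them, B2M by 1.64 from 106 to 328 CPM and HLA-B by 4.31.

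Interferon-stimulated genes rose in 50 of 51 and fell in 0, also adjusted over the list alone, with a median of 3.51 (adjusted p = 5.68e-162). The antiviral GTPase MX1 rose by 9.15, IFIT2 by 8.76, OASL by 8.28, IFI6 by 7.01 and ISG15 by 5.37. CCL5 had 15513 counts against 2, a ratio of 7950 (95% interval 2200 to 65700), and CXCL11 a ratio of 818 (95% interval 226 to 6760). IFNB1 was at least 212-fold, IFNL1 385-fold, IFNL3 501-fold and CXCL10 409-fold higher than in WT, each against 0 counts. Sensing genes rose in 19 of 29 and fell in 4, also adjusted over the list alone (adjusted p = 4.39e-11), IFIH1 by 5.26, RIGI by 3.25 and STING1 by 3.63, while CGAS lay at 1.30 (adjusted p = 0.388). Cytokines rose in 15 of 24 and fell in 3 (16 and 3 adjusted over the list alone, adjusted p = 2.31e-11), CXCL1 by 3.19. MHC class I genes rose in 17 of 21 and fell in 2, also adjusted over the list alone (adjusted p = 3.21e-11), TAP1 by 1.49 and PSMB8 by 2.06. Of 5 MHC class II genes, 4 rose and 0 fell, also adjusted over the list alone, HLA-DMB by 3.12 (adjusted p = 0.0416, adjusted p = 0.295 with an estimated correlation, 0.0529 without WT replicate 1, and 0.0297 to 0.0529 over the alternatives). Checkpoint ligands rose in 10 of 21 and fell in 3 (10 and 6 adjusted over the list alone, adjusted p = 0.0893), CD274 by 2.41 and CEACAM1 by 4.47.

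NF-kB genes rose in 15 of 20 and fell in 1, also adjusted over the list alone, SOD2 by 1.47 (adjusted p = 4.89e-07, and adjusted p = 0.131 with an estimated correlation). AP-1 genes rose in 14 of 26 and fell in 3, also adjusted over the list alone, DUSP6 by 2.97 (adjusted p = 6.22e-05, and adjusted p = 0.155 with an estimated correlation). G2/M genes fell in 34 of 40 and rose in 1 (35 and 1 adjusted over the list alone, adjusted p = 4.56e-07, and adjusted p = 0.421 with an estimated correlation). NRF2 targets fell in 20 of 31 and rose in 6, also adjusted over the list alone, AKR1B10 by 2.92 and EPHX1 by 2.11 (adjusted p = 3.89e-07, and adjusted p = 0.254 with an estimated correlation). The p53 list rose in 22 of 35 and fell in 5 (23 and 5 adjusted over the list alone), MDM2 by 1.09 (adjusted p = 0.00727, and adjusted p = 0.481 with an estimated correlation). The genes of the stress and unfolded protein list fell in 24 of 34 and rose in 5, also adjusted over the list alone (adjusted p = 0.000377, and adjusted p = 0.37 with an estimated correlation). R-loop factors fell in 18 of 40 and rose in 4 (19 and 4 adjusted over the list alone, adjusted p = 0.0569, and 0.0383 to 0.0646 over the alternatives), with a median of -0.209, DDX21 falling by 0.74 and ERCC4 rising by 0.93. The list passed without the genes of chromosomes 2 and 9 (0.0383), and without WT replicates 1 or 3, YTHDF1 KO replicate 2, any siARID1A library, or combined-group replicates 2 or 3 (0.0406 to 0.0498). Epithelial to mesenchymal genes fell in 16 of 31 and rose in 8, also adjusted over the list alone (adjusted p = 0.0548), the matrix protein TGFBI by 2.46 and FN1 (chromosome 2) by 1.77, with the tight junction protein CLDN1 rising by 2.16. Heat shock genes split, 6 up and 5 down of 17, also adjusted over the list alone (adjusted p = 0.978), with a median of -0.022, a mean of 0.099 and a median of 0.114 with library totals.

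FER1L6 (-8.35), NTRK3 (-6.89), TENM2 (-6.40), CYP4F11 (-6.35), OLFML3 (-5.14) and PKDCC (-4.95) had the largest falls within the same limits of level and overlap. Library totals in place of TMM factors raised the median of all genes by 0.135, and 63.4% of the called genes were then higher (6074 against 3505 lower), compared with 49.7%.

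The comparison of the combined group with YTHDF1 KO asked how cells labelled as knocked out for YTHDF1 differed when also labelled for ARID1A silencing. Transcripts of YTHDF1 stood at 28.2% of WT in YTHDF1 KO and 35.1% in the combined group. Interferon-stimulated genes rose further, and MHC class I genes with them. IFIT1 rose by 1.62 (SE 0.047) from 159 to 487 CPM, MX1 by 2.75 (SE 0.062) from 19.1 to 129 CPM and B2M by 0.98 (SE 0.045) from 167 to 328 CPM. IFNB1 rose by 2.7 (SE 0.237) from 0.829 to 5.42 CPM. Of the genes tested, 2315 rose and 2016 fell, 636 and 154 of them by more than 1.

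Interferon-stimulated genes rose in 50 of 51 and fell in 0, also adjusted over the list alone, with a median of 1.36 (adjusted p = 5.02e-138). CMPK2 (chromosome 2) rose by 3.0, IFI27 by 2.28, OAS2 by 2.20, OASL by 1.44 and ISG15 by 1.1. MHC class I genes rose in 16 of 21 and fell in 2, also adjusted over the list alone (adjusted p = 1.17e-16), HLA-B by 2.24 and the class I activator NLRC5 by 1.85. Sensing genes rose in 13 of 29 and fell in 3 (13 and 4 adjusted over the list alone, adjusted p = 3.02e-08), TLR3 by 1.98, IFI16 by 1.60, RIGI by 1.30 and STING1 by 1.63, and CGAS lay at -0.25 (adjusted p = 0.899). Cytokines rose in 10 of 24 and fell in 3 (11 and 3 adjusted over the list alone, adjusted p = 0.0054, and adjusted p = 0.254 with an estimated correlation), CCL5 by 1.61 and CXCL10 by 1.22, with CCL2 falling by 0.99. MHC class II genes rose in 4 of 5 and fell in 0, also adjusted over the list alone, CTSS by 0.88 (adjusted p = 0.00401, and adjusted p = 0.126 with an estimated correlation). CD274 rose by 0.80 (adjusted p = 0.0106, and 0.00184 to 0.0548 over the alternatives), and did not pass without YTHDF1 KO replicate 2 (0.0537) or combined-group replicate 2 (0.0548).

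The p53 list rose in 18 of 35 and fell in 2 (19 and 3 adjusted over the list alone), TP53INP1 by 1.07 and CCNG1 by 0.76 (adjusted p = 9.22e-05, and adjusted p = 0.339 with an estimated correlation). G2/M genes fell in 20 of 40 and rose in 0 (21 and 0 adjusted over the list alone, adjusted p = 2.78e-05, and adjusted p = 0.481 with an estimated correlation). S phase genes fell in 10 of 47 and rose in 1 (11 and 1 adjusted over the list alone), SLBP by 1.16 (adjusted p = 0.000552, and adjusted p = 0.541 with an estimated correlation). Of 34 stress response genes, 15 fell and 2 rose (16 and 3 adjusted over the list alone), PDIA6 by 1.06 and PSAT1 by 0.75 (adjusted p = 0.000178, and adjusted p = 0.347 with an estimated correlation). Histones rose in 13 of 27 and fell in 0, also adjusted over the list alone, H1-2 by 0.95 and H2AC6 by 0.72 (adjusted p = 6.73e-05, and adjusted p = 0.114 with an estimated correlation). DNA repair genes fell in 12 of 50 and rose in 2, also adjusted over the list alone, XRCC5 by 1.53 (adjusted p = 0.00573, and adjusted p = 0.471 with an estimated correlation). R-loop factors fell in 8 of 40 and rose in 1 (10 and 1 adjusted over the list alone), DDX21 by 0.68 (adjusted p = 0.00573, and adjusted p = 0.407 with an estimated correlation).

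Large rises were also seen for the glutathione peroxidase GPX2 (3.04, 39.8 ± 1.37 to 327 ± 61.5 CPM), the cysteine-forming enzyme CTH (3.03) and TM4SF4 (2.96). The keratin KRT80 (-2.42, 76.3 ± 2.04 to 14.1 ± 4.25 CPM), NIPAL4 (-1.70), XRCC5 (-1.53), the Wnt effector CTNNB1 (-1.5) and NPR3 (-1.48) had the largest falls beside ARID1A (-1.57) within these limits. The number of genes that fell was 1303 without replicate 1 of the combined group. With library totals 63.5% of the called genes were higher, compared with 53.5%.

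The comparison of the combined group with siARID1A asked how the knockout cells differed from the others where ARID1A was silenced. Interferon-stimulated genes rose, IFIT1 by 5.32 (SE 0.156) from 12.2 to 487 CPM and ISG15 by 4.55 (SE 0.104) from 7.37 to 173 CPM. The p53 target CDKN1A fell by 1.02 from 459 to 226 CPM and the NRF2 target AKR1C2 by 2.37 from 4850 to 938 CPM. Of the genes tested, 3370 rose and 3193 fell, 757 and 1007 of them by more than 1.

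Interferon-stimulated genes rose in 49 of 51 and fell in 0 (49 and 1 adjusted over the list alone), with a median of 2.73 (adjusted p = 2.12e-167). OAS2 rose by 6.93, OASL by 6.86, IFIT2 by 5.89, IFI27 by 5.52 and IFI44L by 5.48. Cytokines rose in 14 of 24 and fell in 2 (15 and 2 adjusted over the list alone, adjusted p = 2.57e-12), CCL5 by 9.12 and CXCL10 by 6.96, and IFNB1 was at least 179-fold higher. Sensing genes rose in 14 of 29 and fell in 5 (16 and 6 adjusted over the list alone, adjusted p = 1.07e-10), RIGI by 3.01, IFIH1 by 2.95 and STING1 by 2.07. MHC class I genes rose in 15 of 21 and fell in 1, also adjusted over the list alone (adjusted p = 1.72e-07), HLA-B by 2.7, NLRC5 by 2.15 and B2M by 1.41. CD274 rose by 1.38. CGAS fell by 2.69 (adjusted p = 0.0186, and 0.00191 to 0.15 over the alternatives), and did not pass without siARID1A replicate 2 (0.15) or combined-group replicates 2 (0.101) or 3 (0.0625).

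The p53 list fell in 25 of 35 and rose in 2 (27 and 2 adjusted over the list alone), TP53I3 by 1.59 and CYFIP2 by 1.01 (adjusted p = 2.99e-11, and adjusted p = 0.126 with an estimated correlation). NRF2 targets fell in 23 of 31 and rose in 2, also adjusted over the list alone (adjusted p = 2.05e-18, and adjusted p = 0.0652 with an estimated correlation). DNA repair genes rose in 28 of 50 and fell in 0 (29 and 0 adjusted over the list alone), the kinase CHEK2 by 1.03 (adjusted p = 0.000237, and adjusted p = 0.36 with an estimated correlation). R-loop factors rose in 16 of 40 and fell in 4 (16 and 5 adjusted over the list alone, adjusted p = 0.101), with a median of 0.167, ERCC4 rising by 0.72 and DDX1 falling by 0.61. S phase genes rose in 27 of 47 and fell in 1 (29 and 1 adjusted over the list alone), GINS4 by 1.11 (adjusted p = 0.000178, and adjusted p = 0.51 with an estimated correlation). Stress response genes rose in 22 of 34 and fell in 4, also adjusted over the list alone, CRELD2 by 1.21 and HSPA5 by 0.72 (adjusted p = 0.000614, and adjusted p = 0.402 with an estimated correlation). Cholesterol genes rose in 14 of 25 and fell in 2 (14 and 3 adjusted over the list alone), IDI1 by 0.70 (adjusted p = 0.00889, and adjusted p = 0.331 with an estimated correlation). Hippo-YAP targets fell in 13 of 24 and rose in 4, also adjusted over the list alone, ANKRD1 by 2.28 (adjusted p = 0.00312, and adjusted p = 0.451 with an estimated correlation). Hypoxia and glycolysis genes fell in 16 of 36 and rose in 2, also adjusted over the list alone, CA12 by 1.53, with SLC2A3 rising by 1.90 (adjusted p = 0.00251, and adjusted p = 0.34 with an estimated correlation).

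The coagulation factor F5 (-6.70), the urea cycle enzyme CPS1 on chromosome 2 (-4.56, 203 ± 48.7 to 8.57 ± 0.411 CPM), NTRK3 (-4.14), PCSK5 on chromosome 9 (-4.00), SLFN11 (-3.91) and UPK1B (-3.49) fell most among genes within the limits of level and overlap. YTHDF2 and ARID1B rose by 0.24 and 0.42. With library totals 62.2% of the called genes were higher (4328 against 2629 lower), compared with 51.3%.

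The interaction asked whether the change with siARID1A differed between the YTHDF1 backgrounds. It was positive for 1644 genes and negative for 1523. p53 target genes rose less with siARID1A in the knockout than in WT. ARID1A transcripts stood at 25.9% of WT in siARID1A and 33.1% in the combined group, so a weaker knockdown is not told apart from a role of YTHDF1. A difference between WT and the other cultures, as on chromosome 9, is not told apart either. CDKN1A rose by 1.54 with siARID1A in WT and had an interaction of -1.17. HSPA5 fell by 1.43 in WT and had an interaction of 1.16.

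The p53 list was negative for 24 of 35 genes and positive for 0 (28 and 0 adjusted over the list alone), with a median of -0.64 (adjusted p = 2e-22), FDXR at -1.59 and TP53I3 at -1.5. S phase genes were positive for 26 of 47 and negative for 1 (33 and 1 adjusted over the list alone), RFC3 at 0.93 (adjusted p = 1.92e-11, and adjusted p = 0.26 with an estimated correlation). G2/M genes were positive for 24 of 40 and negative for 0 (28 and 0 adjusted over the list alone, adjusted p = 2.64e-09, and adjusted p = 0.347 with an estimated correlation). DNA repair genes were positive for 21 of 50 and negative for 1 (24 and 2 adjusted over the list alone), BRCA2 at 0.91 (adjusted p = 2.76e-06, and adjusted p = 0.254 with an estimated correlation). R-loop factors were positive for 9 of 40 and negative for 0, also adjusted over the list alone, with FANCD2 at 0.69 (adjusted p = 0.00165, and adjusted p = 0.347 with an estimated correlation). Stress response genes were positive for 21 of 34 and negative for 2 (22 and 2 adjusted over the list alone), PSAT1 at 1.14 (adjusted p = 9.32e-14, and adjusted p = 0.106 with an estimated correlation). NF-kB genes were negative for 11 of 20 and positive for 2 (14 and 2 adjusted over the list alone), NFKB2 at -1.12 and PTGS2 at -2.84 (adjusted p = 1.24e-07, and adjusted p = 0.125 with an estimated correlation). Matrix genes were negative for 15 of 36 and positive for 5 (19 and 5 adjusted over the list alone), COL4A5 at -1.44 (adjusted p = 1.98e-06, and adjusted p = 0.217 with an estimated correlation).

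Interferon-stimulated genes went both ways on the log2 scale, 17 of 51 positive and 11 negative (19 and 11 adjusted over the list alone, adjusted p = 0.274), TRIM22 at 2.26 and LGALS3BP at -1.78. IFIT1 had an interaction of -1.08 and IFI6 of -1.07, ISG15 lay at 0.28 (adjusted p = 0.319), STING1 at 0.07 (adjusted p = 0.956) and CD274 at -0.24 (adjusted p = 0.718). MHC class I genes were positive for 5 of 21 and negative for 3 (8 and 3 adjusted over the list alone, adjusted p = 0.0569, and 0.0294 to 0.0993 over the alternatives), B2M at 0.75 and NLRC5 at 1.66. That list passed without the genes of chromosomes 2 and 9 (0.0379). It also passed without WT replicates 2 (0.0351) or 3 (0.0445), YTHDF1 KO replicate 2 (0.0294) or siARID1A replicate 2 (0.0344). For IFNB1, CXCL10 and CCL5, with 0 to 2 counts in WT, no interaction is given. FER1L6 (8.65), PKDCC (2.98), NTRK3 (2.81), ASS1 on chromosome 9 (2.57) and TINAGL1 (2.39) were most positive among genes with a mean of at least 10 CPM, and ANKRD1 (-3.52), FGFBP1 (-2.96) and MYPN (-2.89) among the most negative. Of the 431 expressed genes of chromosome 9, 50.6% had a positive interaction, against 11.1% of genes on the chromosomes other than 2 and 9. The 634 genes of chromosome 17 had a median interaction of -0.15 relative to the others, with 21.6% negative against 11.2% of genes on chromosomes other than 2 and 9. They lay at 0.110, 0.106 and 0.074 in YTHDF1 KO, siARID1A and the combined group, each against WT, and at -0.014 in the combined group vs YTHDF1 KO. The largest median simulated without a shift, for YTHDF1 KO vs WT, was 0.094. That is the largest over all chromosomes, small ones among them, so it sets no limit for chromosome 17. ARID1A itself had an interaction of 0.38 (adjusted p = 0.0278, and 0.00436 to 0.0972 over the alternatives). It did not pass with library totals (0.0512) or without WT replicates 1 or 2, or replicates 2 or 3 of YTHDF1 KO, siARID1A or the combined group (0.0517 to 0.0972).

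**Figure D5:**
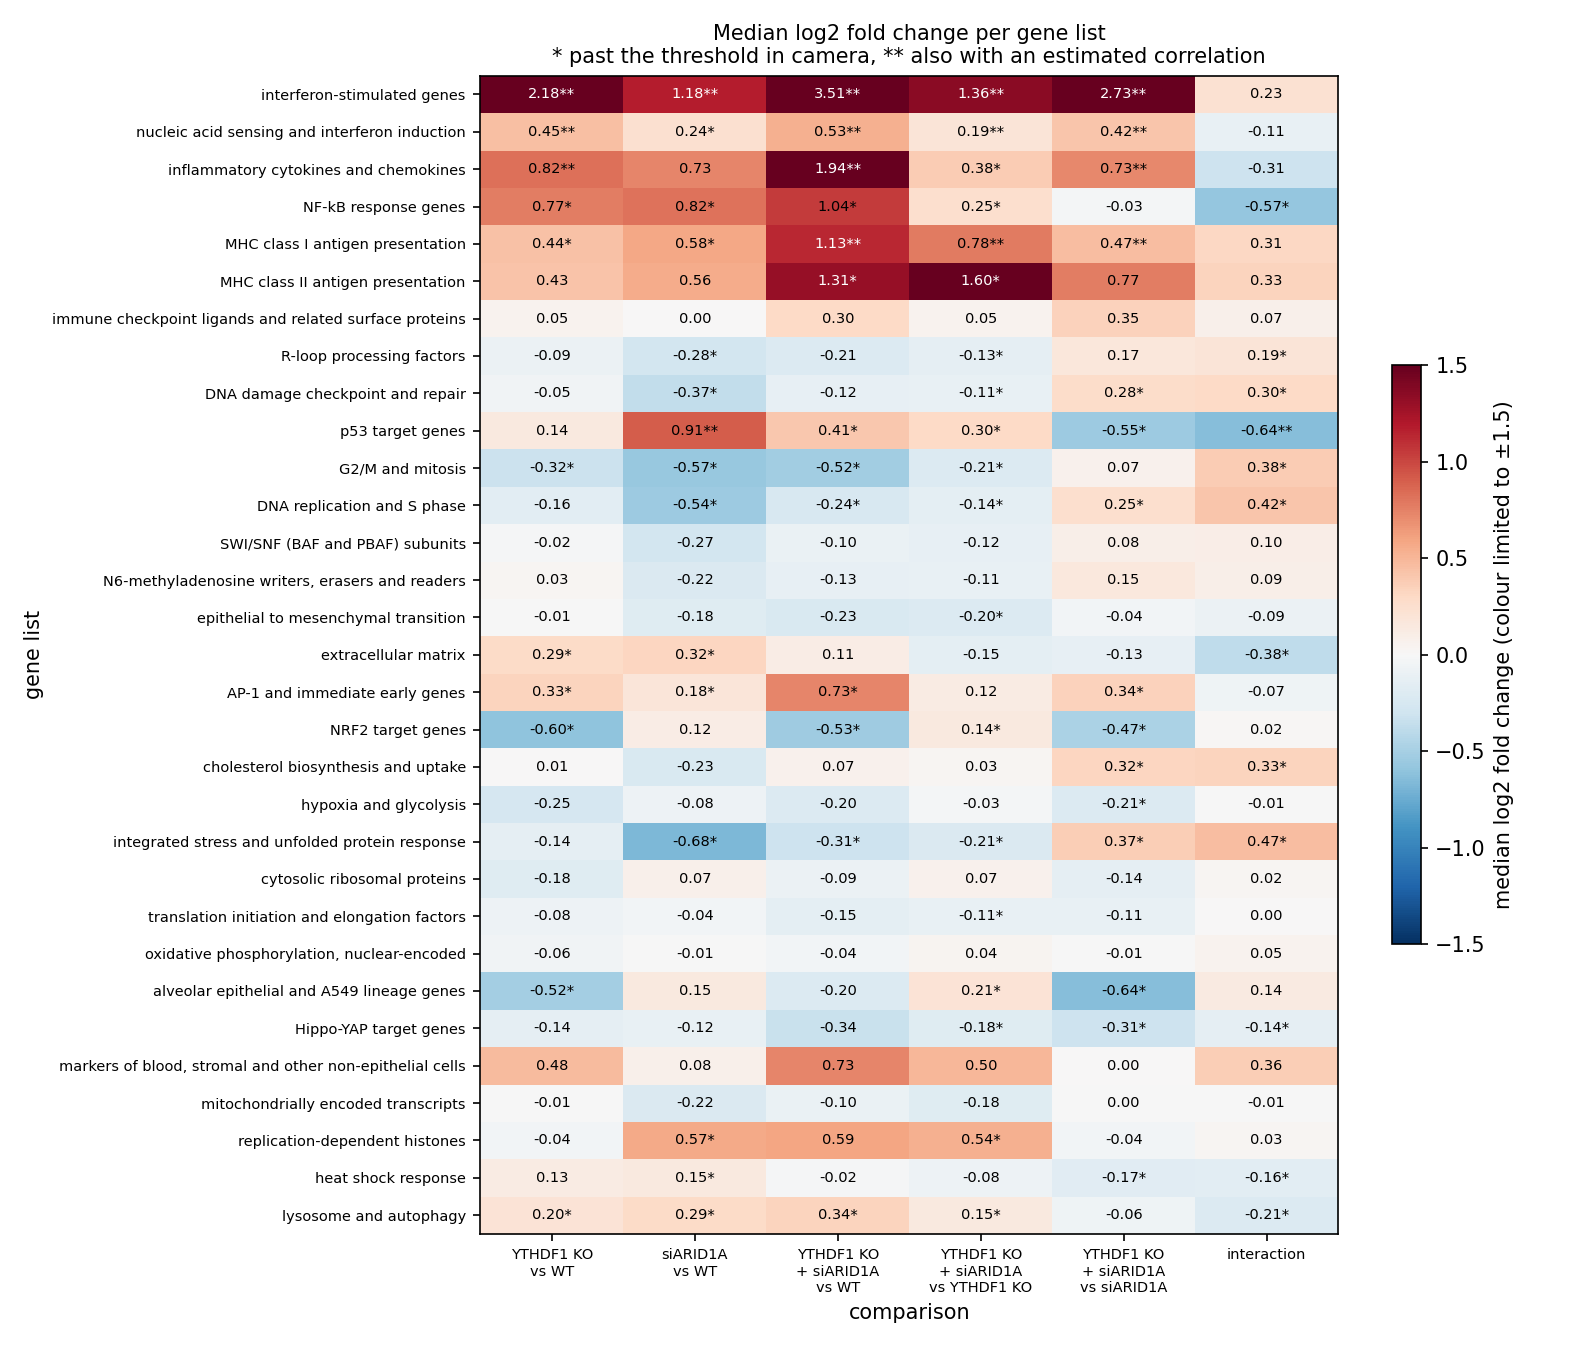
Median log2 fold change of each gene list (y axis) in each comparison (x axis), as numbers and as colour limited to 1.5 in size. A single star marks camera's threshold and a double star that it also held with an estimated correlation. Interferon-stimulated genes have medians of 2.18, 1.18, 3.51, 1.36 and 2.73 in the pairwise comparisons, all with double stars.

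With an estimated correlation, camera's calls held for interferon-stimulated genes in the 5 pairwise comparisons, for sensing genes in all of these but siARID1A vs WT, and for cytokines in YTHDF1 KO vs WT and in the combined group vs WT and vs siARID1A. They also held for MHC class I genes in the 3 comparisons of the combined group, and for p53 targets in siARID1A vs WT and in the interaction. Across genes, which are not independent replicates, the change with siARID1A in WT and that in YTHDF1 KO had r = 0.473 (jackknife SE 0.047). Of the calls of both, 1547 genes were higher and 1458 lower in each (512 and 464 for independent lists), and 201 went opposite ways. The change with YTHDF1 KO without and with siARID1A had r = 0.639 (SE 0.034), with 1930 genes higher and 2011 lower in each (660 and 665 for independent lists), and 313 opposite. Both comparisons hold the chromosome 2 block, with 71.2% of its 715 genes called lower in YTHDF1 KO vs WT and 71.2% in the combined group vs siARID1A. No value without these genes was computed, so their part in this agreement is not known. YTHDF1 KO and siARID1A, each against the same WT libraries, had r = 0.446 (SE 0.106), where unchanged groups gave a median of 0.496 in simulation. Their covariance was 0.42 against a simulated 0.0367, and 1819 genes were higher and 1857 lower in both (803 and 889 for independent lists), with 860 opposite. The lists share WT libraries, so the values for independent lists are not those without a shared response. Simulated unchanged groups gave at most 0 genes higher and 0 lower in both. All simulated groups were drawn from the WT mean, so they hold no WT culture that differs from the rest, as on chromosome 9. A response shared by YTHDF1 KO and siARID1A is not told apart from such a difference. These 3 correlations are the only ones of their kind that were computed.

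Median and mean of a list differed in sign in some comparisons. In YTHDF1 KO vs WT these were N6-methyladenosine factors, cholesterol genes (0.009 and -0.044) and mitochondrially encoded transcripts (-0.011 and 0.071), and DNA repair genes had a median of -0.05 and a mean of -0.013 where camera's direction was up. In siARID1A vs WT they were hypoxia and Hippo-YAP genes (-0.117 and 0.126). In the combined group vs WT they were alveolar (-0.202 and 0.065) and heat shock genes, and in that group vs YTHDF1 KO hypoxia (-0.032 and 0.01) and heat shock genes (-0.077 and 0.084). Against siARID1A they were NF-kB genes (-0.028 and 0.269), matrix genes (-0.127 and 0.163) and mitochondrially encoded transcripts (-0.003 and 0.004), and in the interaction checkpoint ligands (0.073 and -0.03) and translation factors (0.003 and -0.002). Camera's direction was down where both were above 0 for oxidative phosphorylation genes in the combined group vs YTHDF1 KO (0.037 and 0.006), and in the interaction for NRF2 targets (0.023 and 0.006) and markers of other cells (0.365 and 0.232).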

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

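Of the tests in this part, those of the chromosome shifts, of copy number for genes lower with siARID1A, of transfection and of the WT libraries standing apart were chosen after the result was seen, and the 7-mer test and the splits before.

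The test of the difference between the YTHDF1 backgrounds picked out 1644 genes with a positive and 1523 with a negative interaction, on the log2 scale. Among others, these were FER1L6 (8.65), PKDCC (2.98), NTRK3 (2.81), ASS1 (2.57), TINAGL1 (2.39), TRIM22 (2.26), B2M (0.75) and ARID1A (0.38), and, on the negative side, CGAS (-4.24), ANKRD1 (-3.52), FGFBP1 (-2.96), MYPN (-2.89), PTGS2 (-2.84), OAS2 (-2.33), IFIT2 (-1.28) and IFIT1 (-1.08). The same test picked out lists at camera's preset correlation, of which only p53 targets held with an estimated correlation (adjusted p = 0.0318, and adjusted p = 0.106 to 0.501 with an estimated correlation for the others), with medians of 0.47 for the stress and unfolded protein response, 0.42 for S phase, 0.38 for G2/M, 0.33 for cholesterol, 0.30 for DNA repair and 0.19 for R-loop factors. Negative medians were -0.64 for p53 targets, -0.57 for NF-kB genes, -0.38 for matrix, -0.21 for lysosome, -0.16 for heat shock and -0.14 for Hippo-YAP targets. FER1L6, PKDCC, NTRK3 and TINAGL1 fell in both single changes, and FER1L6 stood at 0.193, 0.272 and 0.243 CPM in the 3 groups other than WT. The CGAS value rests on 4, 12, 58 and 10 counts in WT, YTHDF1 KO, siARID1A and the combined group, and its adjusted p of 0.048 ran from 0.0146 to 0.267 over the alternatives. It was over the threshold without any 1 of 10 libraries, and under it without WT replicate 1 or YTHDF1 KO replicate 2.

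The first pattern weighed is the shift of chromosomes 2 and 9. Of the chromosome 2 genes, 88.3% lay below the median of the other chromosomes in YTHDF1 KO vs WT, and of the chromosome 9 genes 79.1% in siARID1A vs WT, along unbroken runs of windows, where regulation of a minority of genes would leave most genes near 0. A difference in copies of these chromosomes between the cultures is a candidate explanation that had these values, but no DNA was measured, and whether the YTHDF1 KO cells were a clone or a pool is not stated. The positive interaction of chromosome 9 genes, 0.404 relative to the others, had the size of their change in siARID1A with the sign turned, as WT libraries apart from the other 3 groups would give. That size follows by arithmetic from their median of 0.000 in the combined group vs YTHDF1 KO, and adds nothing to it. No biological explanation by YTHDF1 or ARID1A was tested, and YTHDF1 KO and siARID1A, which share the chromosome 9 shift, have no labelled change in common. Without the genes of both chromosomes, 3072 genes rose and 3152 fell in YTHDF1 KO vs WT.

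A second pattern is of genes lower with siARID1A in both YTHDF1 backgrounds. Silencing through a seed match of the small interfering RNA may be part of it, since TCAAGAA, the 7-mer lowest in siARID1A vs WT, had a z of -8.21 in the combined group vs YTHDF1 KO, against 0.41 in YTHDF1 KO vs WT. Its z of 3.68 in the combined group vs siARID1A was among the highest, at rank 16075 of 16082 from the lowest. Genes with CTCAAGAA had medians of -0.181 in siARID1A vs WT and -0.106 in the combined group vs YTHDF1 KO. For the interaction of such genes, a weaker seed effect in the knockout is not told apart from a role of YTHDF1. Medians of chromosomes 2 and 9 relative to the others were 0.000 in the combined group vs YTHDF1 KO, which argues against copies of these chromosomes as the cause. Among the 10432 genes summarised by chromosome, 87.4% of those lower in both lay on other chromosomes (1140, against 165). These hold 9286 of the 10432 genes, so that share cannot decide the question. On chromosomes 2 and 9, 14.4% of genes were lower in both, against 12.28% elsewhere. The sequence of the small interfering RNA is not given. Among the 11095 genes of the 7-mer search, 1333 were lower in both. Of these, 37.7% carry either 7-mer of CTCAAGAA, against 27.0% of all genes searched. Most are thus without either 7-mer, and loss of ARID1A stays open for these. It stays open for the carriers too, since a 7-mer in the 3′ UTR does not show that a gene was silenced through it.

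The third pattern is the rise of interferon-stimulated genes with siARID1A. The list's median was 1.359 in the combined group vs YTHDF1 KO, a comparison between groups other than WT. That argues against WT standing apart as the cause of the rise in the knockout background. For the rise in siARID1A vs WT it cannot decide, since that comparison uses the WT libraries. Transfection of a small interfering RNA in itself cannot be told apart from loss of ARID1A, since no label names a control small interfering RNA and the list rose in both backgrounds (the lower median 1.177). Loss of ARID1A stays open as the biological explanation. The rise in YTHDF1 KO vs WT (median 2.18) involves no siARID1A label, and whether those cells were transfected is not stated.

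Each pairwise comparison allows 10 splits of its 6 libraries, too few for a share under 0.05, and in each the real split alone reached the real value (1 of 10). The real splits called 6949, 7218, 8724, 5912 and 6936 genes, in fits of the compared groups alone in the order of the comparisons in the report, and the highest other split 0 each time. For the interaction, 2 of 60 splits, the real one included, called as many genes as the real 3167. The other called 3662 and set the 6 libraries without siARID1A against the 6 with it, so that it measured that difference, and the next highest called 230.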

How the results depend on the processing

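The fits without the genes of chromosomes 2 and 9 and without mitochondrially encoded genes were chosen after the data were seen. All counts of changed genes stayed within 1.5 times their value under the other alternatives run, except that 1303 genes fell in the combined group vs YTHDF1 KO without replicate 1 of the combined group (1303 to 1766 over single libraries left out, 2016 with all). Without that library the group has 2 libraries, and the cause was not tested further. Over single libraries left out, YTHDF1 KO vs WT had 3082 to 3586 genes higher and 3295 to 3797 lower, and siARID1A vs WT 3551 to 4080 and 3634 to 4134. The correlation of the siARID1A change in both backgrounds (0.473) was 0.4 to 0.45 with 1 library left out and 0.641 in genes with a mean of at least 10 CPM. That of the YTHDF1 KO change (0.639) was 0.572 to 0.602 and 0.778. Fits with 1 library left out were filtered anew and held 19120 to 19329 genes. The cause of these differences was not tested.

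Of 186 list tests, 85 passed in camera. The estimated correlation ended 68 of these, the replicate block 1 (alveolar genes in the combined group vs siARID1A, 0.0602), RLE factors 0, and the fit without chromosomes 2 and 9 ended 6 and added 8. The 6 were matrix (0.253) and lysosome genes (0.215) in YTHDF1 KO vs WT, sensing (0.119) and AP-1 genes (0.0629) in siARID1A vs WT, and alveolar (0.289) and NF-kB genes (0.0518) in the combined group vs YTHDF1 KO. Without WT replicate 2, the library with the low mitochondrial share, 20 of the 186 list tests newly passed, 1 no longer did and 2 turned direction, for which the cause was not tested. The latter were ribosomal proteins in siARID1A vs WT (0.00234, and 0.00234 to 0.974 over single libraries left out) and mitochondrially encoded transcripts in the interaction (0.0475, and 0.0475 to 0.73). Calls in the combined group vs YTHDF1 KO that ended with 1 library left out were alveolar genes (0.0497, highest with a library left out 0.0546), NF-kB genes (0.0358, highest 0.0591), NRF2 targets (0.0226, highest 0.0728), epithelial to mesenchymal genes (0.0348, highest 0.0929) and translation factors (0.0327, highest 0.0905). In siARID1A vs WT they were sensing genes (0.0306, and 0.0507 without siARID1A replicate 2), AP-1 genes (0.0327, and 0.0908 without WT replicate 1) and heat shock genes (0.0416, and 0.0724 without WT replicate 3).

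Library totals turned the sign of medians only of lists that had not passed, among them DNA repair in YTHDF1 KO vs WT (-0.05 to 0.045) and N6-methyladenosine factors in the combined group vs WT (-0.127 to 0.007). Of 824 tests of named genes, library totals ended 15 calls and added 6, limma-voom 11 and 1, the replicate block 8 and 1, and DESeq2 3 and 5. Replicate numbers carried no shared signal, with r between residuals of like numbers of -0.042 to 0.033. With counts thinned to the smallest library, YTHDF1 KO vs WT had 3546 genes higher and 3760 lower.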

Other observations

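The comparisons of histones with SLBP, of interferon-stimulated genes with the sum of the single changes, and of ARID1A's own transcript with the 7-mers were chosen after the results were seen.

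In the siARID1A groups, some replication-dependent histones rose and SLBP, whose product binds the 3′ ends of their transcripts, fell. SLBP stood at 63.2 CPM in WT and 66.5 in YTHDF1 KO, and at 20.3 in siARID1A and 29.9 in the combined group. Of 27 histones, 10 rose in siARID1A vs WT (median 0.57, adjusted p = 0.03, and adjusted p = 0.347 with an estimated correlation) and 13 in the combined group vs YTHDF1 KO (median 0.54, adjusted p = 6.73e-05, and adjusted p = 0.114 with an estimated correlation). The SLBP 3′ UTR holds neither 7-mer of CTCAAGAA.

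On the scale of CPM, 50 of 51 interferon-stimulated genes were higher in the combined group than the sum of the single changes, with a median ratio of 2.1. On the log2 scale of the interaction, 17 were positive and 11 negative, with a median of 0.232. The median log2 fold changes of the 45 members outside chromosomes 2 and 9 were 2.18, 1.18, 3.51, 1.36 and 2.73 in the pairwise comparisons.

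ARID1A's own transcript holds CTCAAGA once, ahead of the 3′ UTR, and neither TCAAGAA nor the 8-mer. Of 693 transcripts of like length, 375 hold CTCAAGA at least once anywhere. Of 33 genes below -1 with siARID1A in both backgrounds, 7 carry the 8-mer in their 3′ UTR (21.2%, against 5.4% of all genes searched), among them KRT80, XRCC5, CTNNB1, PDIA6 and CLCN4.

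Transcripts of the YTHDF1 gene remained at 28.2% of WT in YTHDF1 KO, and the counts do not show whether they encode a protein.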
